A study of Mus musculus with 6 samples.

How the data were processed

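Gene expression was compared between 3 libraries of mouse ALL with Kras G12D and 3 with wild-type Kras. Per the labels' protocols, polyadenylated RNA was selected from total RNA, libraries were made with a TruSeq RNA kit that is not named as stranded, and paired-end reads of 100 bp were produced. The submitters' processing notes name bcl2fastq 1.8.4, TopHat, Cufflinks 2.0.2 and the mm9 genome build. The version of TopHat and the gene annotation are not given in the sources used here. The deposited values are FPKM per gene with the lower and upper bound of an interval, also in FPKM, per the file headers. FPKM is scaled to the fragments mapped in each library, so a change in a few abundant genes shifts all others, and it carries no raw counts. Deposited FPKM summed to 443734 to 449099 in Kras G12D and 461757 to 463045 in Kras WT. Each file held 285 rows marked as low in data and 6 to 12 marked as failed; these rows were used as deposited.

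The deposited interval matched counting noise. The fragment number it implies was whole within 0.02 for 73.4% of low values, against 4% if spread evenly. Implied fragments totalled 25870000, 25120000 and 25990000 in Kras G12D replicates 1 to 3 and 30010000, 29970000 and 30890000 in Kras WT replicates 1 to 3. These numbers are estimates, and they served only for depth and for alternatives. Between replicates, the median squared difference was 1.21 to 1.79 times that of counting noise, against at least 19.0 between groups. Over rows of more than 3000 implied fragments it was 1.49 to 1.72 times in Kras WT and 2.42 to 4.14 times in Kras G12D, so replicates differed by more than counting noise, and each library was kept as 1 sample. Correlations of log2 values were 0.994 to 0.997 within groups and 0.959 to 0.961 between groups.

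Rows sharing a symbol were added, and genes with an FPKM of at least 1 in at least 3 libraries were kept, leaving 10797. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with group as the single term and an intensity trend in eBayes. Tests were two-sided with Benjamini-Hochberg adjustment, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Ratios of FPKM means are named as such. Of 47 gene lists, 42 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Of 17 lists past the threshold at the preset correlation, 0 passed with an estimated correlation, and 38 of 42 passed fry, which does not compare a list with other genes. Of 973 list entries, 943 were found by symbol, 8 by an older symbol and 17 not at all; 5 were further names of a gene already in the list.

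The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The text names Kras. It then names the 12 largest increases and the 12 largest decreases among genes that passed, whose replicates did not overlap between groups and whose higher mean was at least 1 FPKM. Genes without an assigned name were passed over, which left out 1 higher gene. For each list described, up to 4 members with the smallest p are named, passed or not. The exceptions are marked in the text as named after their values were seen. Alternatives covered the pseudocount, the filter, scaling, the replicate block, the variance model, library weights, duplicate symbols, quantification status and each library left out. Limma-voom on implied fragments, as they stood and thinned to 1 depth, and removal of trends with GC content and length were chosen after seeing the data. GC content and length came from a GRCm38 annotation and covered 98.9% of tested genes; no coordinates were taken from it. Coordinates are those of the files, in mm9. Their starts count from 0, as 572 of 586 microRNA lengths showed, and are printed from 1.

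The tests were first tested on simulated data for the 10797 genes, with 50 genes changed at each size. For the comparison of Kras G12D with Kras WT, 22% of changes of 0.1 on the log2 scale were recovered, 74% of 0.25, 92% of 0.5 and 98% of 1. Of 10597 unchanged genes, 10 were called. Few genes were changed in the simulation and the noise was independent between genes, whereas 7552 genes were called in the real libraries. The adjusted p depends on the share of changed genes, so these recovery values describe the simulated setting and not the real comparison. Camera called the 1 changed list and 0 lists when none was changed. This result cannot decide whether the list calls on the real libraries hold, since those calls depended on the correlation assumed between genes. There, 17 lists passed at the preset correlation and 0 with an estimated correlation. Python 3.11.15 was used for tables and figures. Alleles were not separated, and reads were not analysed here.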

Results

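Polyadenylated RNA was sequenced from 6 libraries of mouse acute lymphoblastic leukemia (ALL) with spleen as the source, 3 from leukemia cells with Kras G12D and 3 from isogenic leukemia cells with wild-type Kras. KRAS is a small GTPase upstream of the RAF, MEK and ERK kinases, and G12D is an activating substitution found in many cancers. The wild-type group was listed with the mutant allele behind a lox-stop-lox cassette, a transcription stop that Cre recombinase can remove. The comparison asks which transcripts differ between leukemia cells that express the mutant allele and those that do not. Expression was given as FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for 23699 rows and 23235 gene symbols. Between 10599 and 10679 symbols per library reached 1 FPKM. The fragment numbers implied by the deposited intervals came to 25120000 to 25990000 per Kras G12D library and 29970000 to 30890000 per Kras WT library. The median SD between replicates on the log2(FPKM + 1) scale was 0.042 in Kras G12D and 0.033 in Kras WT. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

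Kras itself was higher in Kras G12D, at 50.5 FPKM ± 1.18 (SD, n = 3) against 33.3 FPKM ± 0.475 (SD, n = 3) in Kras WT. The ratio of the means was 1.52, and each of the 3 Kras G12D libraries, at 49.3 to 51.6 FPKM, lay above each Kras WT library, at 32.8 to 33.8 FPKM. The log2 fold change was 0.59 with an SE of 0.024 (limma, adjusted p = 1.0e-07). A two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Kras lies on chromosome 6 at 145165219 to 145198751 of mm9 and overlapped no other gene in the files. Gene-level values do not separate transcripts of the mutant and the wild-type allele, so they check the labels only through the output of the whole locus.

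Large differences included higher Angpt1, Cd44 and S100a4 and lower Slc6a4, Ptgs1 and Rag1 in Kras G12D. Angpt1, which encodes a ligand of the TEK receptor (chromosome 15, 42256271 to 42508341), stood at 100.4 FPKM ± 2.50 (SD, n = 3) against 6.54 FPKM ± 0.239 (SD, n = 3) in Kras WT. Cd44, a hyaluronan receptor and adhesion molecule (chromosome 2, 102651300 to 102741822), stood at 62.9 FPKM ± 0.295 against 4.70 FPKM ± 0.138. The calcium-binding protein gene S100a4 reached 149 FPKM ± 2.95 against 11.9 FPKM ± 2.57, and Gem, a small GTPase gene, reached 173 FPKM ± 6.12 against 21.5 FPKM ± 0.885. Sox13, a transcription factor gene, rose from 5.19 to 61.7 FPKM, and the chemokine receptor gene Ccr8 rose from 1.31 to 18.2 FPKM. Sparc, Cpa3, Tnfrsf19, Capn2 and Slc15a1 were below 1 FPKM on average in Kras WT and between 11.6 and 16.3 FPKM in Kras G12D. Farp1 rose from 1.36 to 17.8 FPKM.

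In the other direction, the serotonin transporter gene Slc6a4 (chromosome 11, 76812099 to 76845845) fell to 5.15 FPKM ± 0.310 (SD, n = 3) from 140.1 FPKM ± 0.726 (SD, n = 3), a log2 fold change of -4.52 with an SE of 0.035 (limma, adjusted p = 3.7e-11). Ptgs1, the gene of cyclooxygenase 1, fell to 1.71 FPKM from 41.3 FPKM, and the proglucagon gene Gcg fell to 5.01 FPKM from 91.1 FPKM. Rag1, a recombinase of antigen receptor genes (chromosome 2, 101478411 to 101489689), fell to 1.70 FPKM ± 0.086 from 26.3 FPKM ± 0.864. Myl10 and Fap fell to 5.95 and 3.90 FPKM from 61.0 and 36.6 FPKM. Khdc1a fell to 1.79 FPKM from 24.3 FPKM; it belongs to a family of similar genes, so its value is uncertain where reads could be shared. Tgm2, Insc and Plxdc2 lay at 0.780, 0.439 and 0.559 FPKM in Kras G12D and at 17.8, 12.4 and 11.1 FPKM in Kras WT. Angpt2, which overlaps the Mcph1 locus in libraries not stated to mark strand, was at 0.120 FPKM against 7.30 FPKM. Some genes named below also overlap another locus, among them Cxcr6 (Fyco1), Itgae (Gsg2) and Tpi1 (Spsb2), and carry the same limit. Psg17 was listed at 0, 0.021 and 0 FPKM in the Kras G12D libraries and at 8.14 to 8.68 FPKM in Kras WT.

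**Figure D1:**
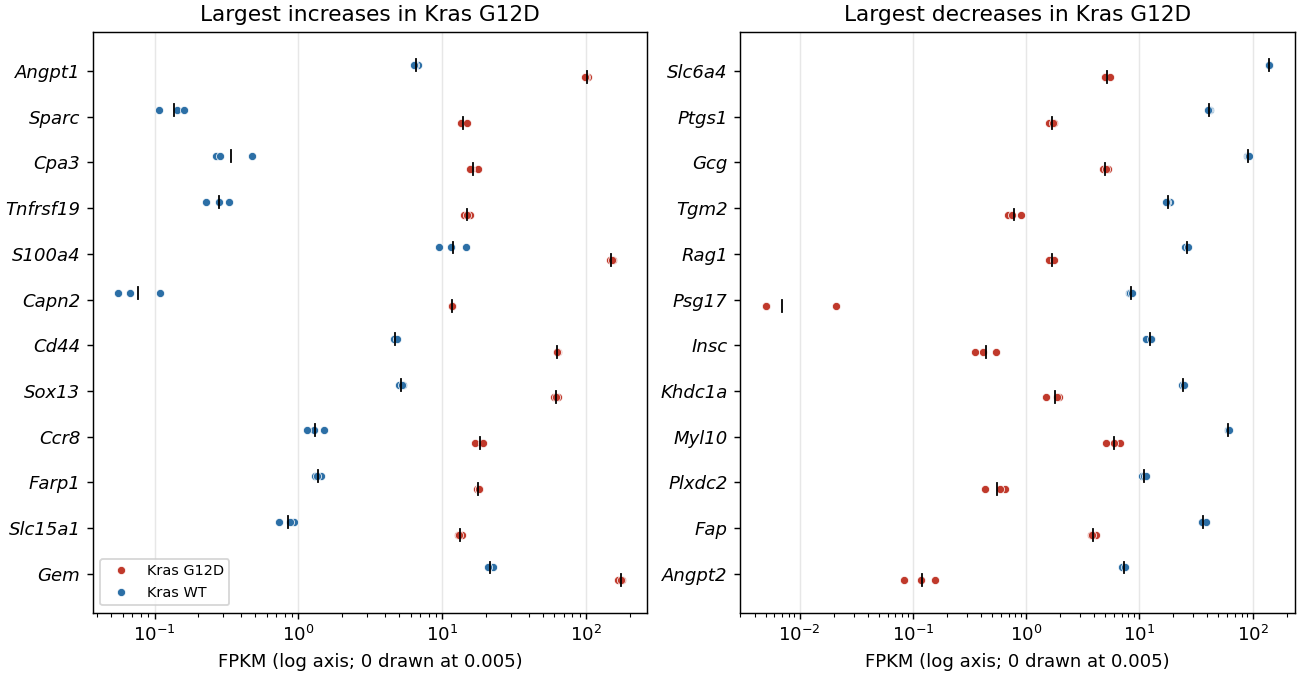
FPKM per library, on a log axis, of the 12 named genes with the largest increase and the 12 with the largest decrease in Kras G12D; points are libraries, black bars are group means, and values of 0 are drawn at 0.005. The naming rule asked for Kras G12D and Kras WT libraries that do not overlap, so their separation here is no support for these genes. Before ranking, 3335 higher and 4090 lower genes met the conditions of the rule, those without an assigned name included. Angpt1 stood at 100.4 against 6.54 FPKM on average.

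Of 10797 genes tested, 7552 changed (limma, adjusted p under 0.05), with 3379 higher and 4173 lower in Kras G12D. That is 69.9% of tested genes, so counts of changed list members below, rises and falls together, are to be read against this share. Rises alone are to be read against 3379 of 10797 genes, and falls alone against 4173 of 10797. Most changes were small: the median absolute log2 fold change among called genes was 0.25, and 498 genes changed at least 2-fold on the log2(FPKM + 1) scale, 288 higher and 210 lower. That count was 193 with a pseudocount of 5, 270 at a mean FPKM of at least 5 and 750 by limma-voom. After rescaling each library to TPM the balance turned, with 4304 genes higher and 3496 lower among 7800 calls. The first principal component held 87.1% of the variance and separated the groups.

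Genes induced by ERK signalling were higher in Kras G12D. Of 15 tested members of the ERK feedback and output list, 12 rose, 2 fell and 1 did not pass, with the same numbers adjusted over the list alone, and the median log2 fold change was 1.04. Dusp6, the gene of an ERK phosphatase, rose to 41.4 FPKM ± 0.226 (SD, n = 3) from 5.42 FPKM ± 0.224 (SD, n = 3). The ETS factor gene Etv5 rose to 255.7 FPKM ± 3.60 from 79.7 FPKM ± 0.261, and the receptor kinase gene Epha2 rose to 11.5 FPKM from 1.02 FPKM. Ccnd1, which encodes cyclin D1, fell to 35.2 FPKM ± 0.933 from 78.8 FPKM ± 0.148, and Phlda1, named after its value was seen, fell to 4.30 FPKM from 8.46 FPKM. The list passed camera at an adjusted p of 0.00010, and had an adjusted p = 0.10 with an estimated correlation. Among 30 Ras and MAPK pathway components, 18 rose, 5 fell and 7 did not pass, also adjusted over the list alone. Rasa2 and Rasa3, which encode GTPase-activating proteins of RAS, rose to 30.3 and 48.8 FPKM from 14.1 and 29.8 FPKM, and the adaptor gene Grb2 rose to 186 FPKM from 116 FPKM. Rasgrp1, a RAS exchange factor gene, fell to 117 FPKM from 198 FPKM. This list had an adjusted p of 0.011 in camera and an adjusted p = 0.18 with an estimated correlation.

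Cell cycle genes were lower in Kras G12D. All 30 tested DNA replication and G1/S genes fell, also adjusted over the list alone, with a median log2 fold change of -0.38. The ribonucleotide reductase genes Rrm1 and Rrm2 fell to 94.8 and 120 FPKM from 136 and 174 FPKM, and E2f2 fell to 12 FPKM ± 0.296 (SD, n = 3) from 24.5 FPKM ± 0.227 (SD, n = 3). Of 31 mitotic and G2/M genes, 28 fell and 3 did not pass, also adjusted over the list alone, and the spindle checkpoint gene Bub1b fell to 59.3 FPKM from 96.5 FPKM. Of 23 DNA repair genes, 21 fell and 2 did not pass; adjusted over the list alone, 21 fell and 1 rose. Lig1, which encodes DNA ligase I, fell to 86.3 FPKM from 143 FPKM. The camera adjusted p was 3.9e-09 for replication, 1.0e-06 for mitosis and 9.0e-05 for repair. These lists had an adjusted p = 0.076, 0.077 and 0.15 with an estimated correlation, in that order.

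The ATF4 and amino acid list and the MYC and ribosome biogenesis list were lower as well. Of 23 ATF4 and amino acid genes, 22 fell and 1 rose, also adjusted over the list alone, with a median log2 fold change of -0.74. Asns, which encodes asparagine synthetase (chromosome 6, 7625171 to 7643182), fell to 119.9 FPKM ± 0.720 (SD, n = 3) from 250.0 FPKM ± 1.31 (SD, n = 3). Chac1, Mthfd2 and Phgdh fell to 17.7, 63.2 and 67.8 FPKM from 39.6, 121 and 114 FPKM. The member that rose, named after its value was seen, was Aldh18a1, at 186 FPKM against 174 FPKM. Of 27 MYC and ribosome biogenesis genes, 24 fell, 1 rose and 2 did not pass, also adjusted over the list alone; the nucleolar protein gene Nop56 fell to 88.0 FPKM from 134 FPKM, and the transferrin receptor gene Tfrc rose to 127 FPKM from 91.1 FPKM. The camera adjusted p was 2.3e-08 for the ATF4 list and 9.2e-06 for the MYC list. They had an adjusted p = 0.18 and 0.077 with an estimated correlation.

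Of 29 oxidative phosphorylation genes, 24 fell and 2 rose, and of 20 glycolysis genes, 14 fell and 5 rose, also adjusted over each list alone. The glycolytic enzyme gene Tpi1 fell to 268 FPKM from 523 FPKM, while the hexokinase gene Hk2 rose to 32.0 FPKM ± 0.686 (SD, n = 3) from 13.9 FPKM ± 0.445 (SD, n = 3). Of 15 folate and methotrexate genes, 11 fell and 2 rose, and of 18 tubulin and vincristine genes, 14 fell and 2 rose, also adjusted over each list alone. Slc19a1, the gene of the reduced folate carrier, fell to 5.03 FPKM from 8.72 FPKM, and Aldh1l1 rose to 3.20 FPKM from 1.06 FPKM. Tuba4a fell to 96.8 FPKM from 203 FPKM, and Mtap4 rose to 27.4 FPKM from 13.9 FPKM. The camera adjusted p was 0.00035 for oxidative phosphorylation, 0.013 for glycolysis, 0.013 for folate and 0.012 for tubulin. They had an adjusted p = 0.42, 0.33, 0.19 and 0.35 with an estimated correlation. Of 35 cytosolic ribosomal protein genes, 23 fell and 12 did not pass, and 22 fell adjusted over the list alone (camera, adjusted p = 0.0049; adjusted p = 0.31 with an estimated correlation). Rps2 fell to 389 FPKM from 544 FPKM. The median log2 fold change was -0.18 for oxidative phosphorylation, -0.42 for glycolysis and -0.16 for ribosomal protein genes. It was -0.17 for 12 housekeeping genes, a list of sample quality that did not pass camera (adjusted p = 0.16). The falls in oxidative phosphorylation and ribosomal protein genes were thus no larger than about that of housekeeping genes. Ribosomal protein genes have many processed copies, so their values are uncertain, and the call ended once trends with transcript GC content and length were removed (adjusted p = 0.17).

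**Figure D2:**
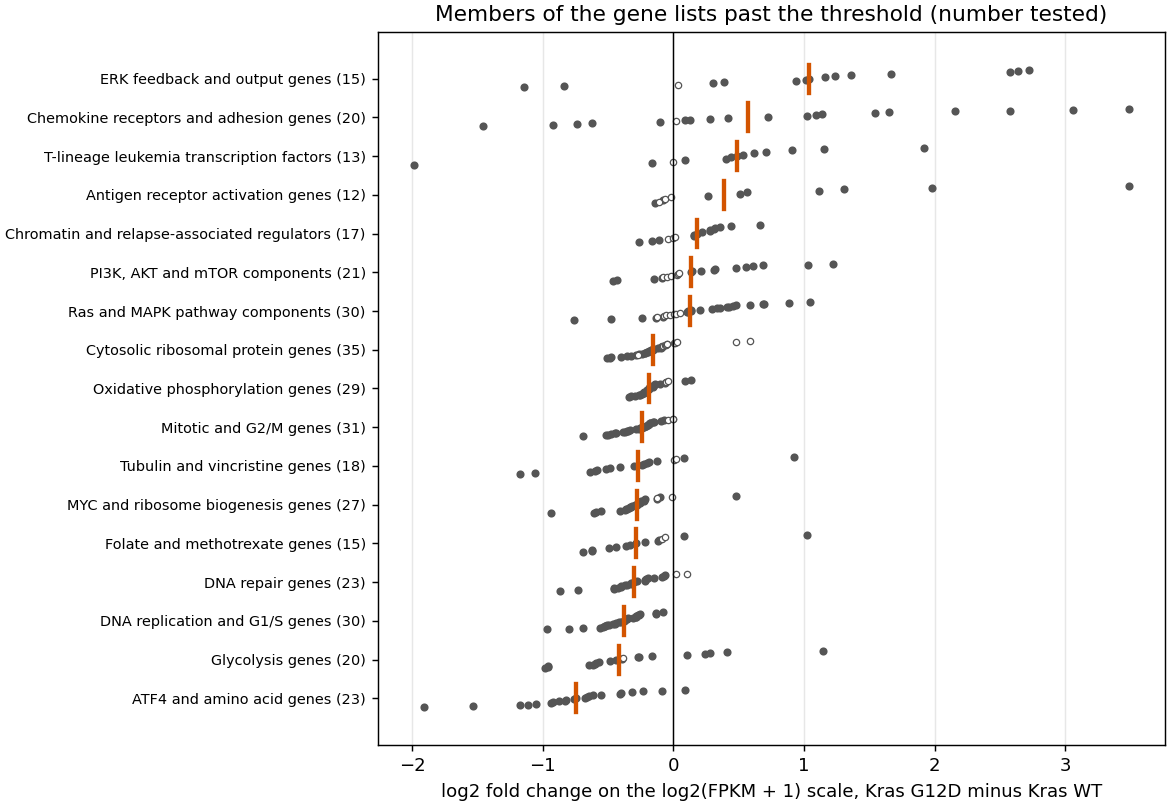
Log2 fold change on the log2(FPKM + 1) scale, Kras G12D minus Kras WT, of each tested member of the 17 gene lists past the camera threshold at the preset correlation; filled points passed limma at an adjusted p under 0.05, open points did not, and orange bars are list medians. List medians ran from -0.74 for the ATF4 and amino acid genes to 1.04 for the ERK feedback and output genes.

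The lists of T-lineage leukemia transcription factors, of chemokine receptors and adhesion, and of antigen receptor activation were higher in Kras G12D at the preset correlation. Of 13 tested T-lineage leukemia transcription factors, 10 rose, 2 fell and 1 did not pass, also adjusted over the list alone. Runx3 rose to 24.1 FPKM ± 0.952 (SD, n = 3) from 5.64 FPKM ± 0.239 (SD, n = 3), Ikzf3 and Gata3 rose to 76.4 and 145 FPKM from 40.3 and 99.8 FPKM, and Lyl1 fell to 2.70 FPKM from 13.6 FPKM. Of 20 chemokine receptor and adhesion genes, 14 rose, 5 fell and 1 did not pass, also adjusted over the list alone. Cxcr6 rose to 73.1 FPKM from 11.4 FPKM, the integrin gene Itgb7 rose to 58.9 FPKM from 12.4 FPKM, and Itgae fell to 64.1 FPKM from 178 FPKM. Of 12 antigen receptor activation genes, 7 rose and 2 fell, also adjusted over the list alone; Cd5 rose to 69.8 FPKM from 27.6 FPKM and Nr4a1 to 16.4 FPKM from 7.02 FPKM. The camera adjusted p was 0.0016 for the transcription factors, 0.0038 for chemokine receptors and adhesion and 0.027 for activation. They had an adjusted p = 0.18, 0.21 and 0.21 with an estimated correlation.

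Among 17 chromatin and relapse-associated regulators, 11 rose and 3 fell, and among 21 PI3K, AKT and mTOR components, 11 rose and 4 fell, also adjusted over each list alone. Dnmt3a, a DNA methyltransferase gene, rose to 59.6 FPKM from 37.3 FPKM. Deptor, an inhibitor of mTOR, and Foxo1 rose to 64.8 and 12.4 FPKM from 31.1 and 4.72 FPKM. The camera adjusted p was 0.035 for each list, and they had an adjusted p = 0.42 and 0.21 with an estimated correlation. Removing trends with GC content and length ended both calls (adjusted p = 0.19 and 0.20), and the chromatin call also ended without Kras G12D replicate 1 (adjusted p = 0.0505).

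NOTCH1 target, BCL2 family, JAK-STAT and glucocorticoid response genes changed in both directions, and these lists did not pass camera. Of 15 NOTCH1 target genes, 5 rose and 10 fell, also adjusted over the list alone (camera, adjusted p = 0.17). Ptcra, which encodes the pre-T cell receptor alpha chain, fell to 2.77 FPKM ± 0.061 (SD, n = 3) from 19.98 FPKM ± 0.288 (SD, n = 3). Of 20 BCL2 family and apoptosis genes, 8 rose and 6 fell, also adjusted over the list alone (camera, adjusted p = 0.88). Bcl2l1, the gene of BCL-XL, fell to 13.4 FPKM ± 0.837 from 56.8 FPKM ± 0.885, and Bcl2 rose to 38.2 FPKM ± 1.18 from 21.3 FPKM ± 0.499. The pro-apoptotic genes Bcl2l11 and Bik went apart, with Bcl2l11 at 27.9 against 43.0 FPKM and Bik at 5.41 against 0.557 FPKM. Of 19 JAK-STAT and cytokine signalling genes, 9 rose and 8 fell, and 9 rose and 9 fell adjusted over the list alone (camera, adjusted p = 0.96). Cish, a feedback gene of STAT5, fell to 3.14 FPKM from 22.2 FPKM, Il4ra fell to 2.76 FPKM from 16.0 FPKM, and the interleukin 7 receptor gene Il7r fell to 0.336 FPKM from 4.28 FPKM, while Il2rg rose to 159 FPKM from 111 FPKM. All 14 glucocorticoid response genes changed, 9 higher and 5 lower, also adjusted over the list alone (camera, adjusted p = 0.16, and 0.047 among genes at a mean FPKM of at least 5). The glucocorticoid list had an adjusted p = 0.44 with an estimated correlation.

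Of 19 purine and thiopurine genes, 13 fell and 2 rose, also adjusted over the list alone, and the median log2 fold change was -0.21. Paics and Prps1, genes of enzymes in purine synthesis, fell to 122 and 27.5 FPKM from 163 and 36.7 FPKM. The list missed the threshold (camera, adjusted p = 0.054). It passed after rescaling to TPM (0.048), with no filter (0.015), at a mean FPKM of at least 5 (0.015) and without Kras G12D replicate 3 (0.045), and had an adjusted p = 0.22 with an estimated correlation.

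Markers of the T lineage were abundant in both groups, while lists of other cell types differed in how many members were detected. Cd3e stood at 602 against 510 FPKM and Lck at 354 against 331 FPKM, while Cd4 was at 0.342 against 0.336 FPKM; these 3 were named after their values were seen. Of 22 tested T cell and thymocyte markers, 11 rose and 8 fell, also adjusted over the list alone (camera, adjusted p = 0.61). Cd6 rose to 103 FPKM from 24.5 FPKM and Cd7 fell to 52.9 FPKM from 125 FPKM. Of 19 B cell markers, 14 were under 1 FPKM in both groups, among them Cd79a, Cd19 and Ms4a1, also named after their values were seen. Of the 5 tested, 2 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.77), with Blk at 44.4 against 8.50 FPKM, Spib at 86.1 against 240 FPKM and Cd79b at 2.79 against 4.27 FPKM. Of 22 monocyte, macrophage and dendritic cell markers 19 were under 1 FPKM in both groups, as were 15 of 17 neutrophil markers, 18 of 20 stromal and endothelial markers and 11 of 12 megakaryocyte and platelet markers. Fewer members lay under 1 FPKM in both groups for the plasma cell list (3 of 8), the NK and cytotoxic list (6 of 14), the erythroid list (8 of 16) and the haematopoietic progenitor list (9 of 14). Xbp1, Prdm1 and Sdc1 of the plasma cell list stood at 50.24, 1.34 and 23.02 FPKM against 66.89, 0.089 and 19.14 FPKM, and Klf1 and Trfr2 of the erythroid list at 11.1 and 13.9 FPKM against 17.9 and 11.5 FPKM. Ly6a, Gata2 and Kit of the progenitor list, which also holds Angpt1, stood at 36.3, 12.9 and 100.4 FPKM against 98.8, 3.60 and 78.2 FPKM. Of 5 tested plasma cell markers, 2 rose and 1 fell, and of 5 progenitor markers, 3 rose and 1 fell, also adjusted over each list alone (camera, adjusted p = 0.88 and 0.16). Of 7 erythroid markers, 1 rose and 2 fell, and 1 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.89). The stromal exceptions were Pdgfrb, at 201 against 110 FPKM, and Pecam1, at 40.9 against 24.9 FPKM. Of 8 tested NK and cytotoxic cell markers, 3 rose and 5 fell, also adjusted over the list alone (camera, adjusted p = 0.40). The granzyme gene Gzma fell to 2789 FPKM ± 67.7 (SD, n = 3) from 5624 FPKM ± 96.0 (SD, n = 3) and Tbx21, the gene of T-bet, to 0.557 FPKM from 7.09 FPKM, while Il2rb rose to 38.4 FPKM from 29.0 FPKM. Of 12 housekeeping genes, 8 fell and 2 rose, also adjusted over the list alone (camera, adjusted p = 0.16), with Gapdh at 259 against 341 FPKM and Actb at 1479 against 1157 FPKM.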

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

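Limma-voom on implied fragments and the removal of GC and length trends were chosen after seeing the data. Kras stayed higher under all 22 alternatives run for it, with log2 fold changes of 0.54 to 0.65. The 24 genes with the largest changes kept their direction and side of the threshold in all 526 values computed. The count of changed genes ran from 7033 to 7443 with 1 library left out, against 7552, and was 7513 under median-of-ratios scaling, 7507 under quantile normalization and 7800 after rescaling to TPM. The median log2 fold change of all genes ran from -0.0335 at a mean FPKM of at least 5 to 0.0224 in TPM. With the replicate block the count was 7473. Deviations of same-numbered libraries correlated at 0.070, 0.050 and -0.17, and not every library correlated best with its own number. These values show no pairing by number. They cannot exclude a small shared effect, since replicates differed little beyond counting noise.

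The count of genes changed at least 2-fold depended on the pseudocount and the filter: 498 became 721 with a pseudocount of 0.1, 193 with a pseudocount of 5, which shrinks changes of low genes, and 270 at a mean FPKM of at least 5, where fewer genes were tested. It was 500 under median-of-ratios scaling and 485 under quantile normalization. It was 703 in TPM (439 higher, 264 lower), where values are larger, so the pseudocount weighs less and 11468 genes pass the filter, and 750 by limma-voom, thinned or not, which uses no such pseudocount; these alternatives change several choices at once. Asking for at least 2-fold beside the adjusted p left 498 changed genes. The number of lists past the threshold fell from 17 to 0 with an estimated correlation and rose to 38 with fry. Fry gave the other direction for BCL2 family genes (adjusted p = 0.0030), JAK-STAT genes (0.00011) and T cell markers (0.0014), whose medians and means differ in sign. Cd68, at 1.45 against 1.46 FPKM, did not pass (log2 fold change -0.0042) and changed sign to 0.0077 under median-of-ratios scaling, 0.037 in TPM, 0.067 without GC and length trends, 0.0053 with library weights, 0.030 by limma-voom and 0.047 by limma-voom after thinning. Leaving out 1 library moved it between -0.072 and 0.10; the cause was not tested. Apart from fry and the estimated correlation, 10 list values newly passed and 4 no longer passed, and among other named genes 3 newly passed and 16 no longer passed.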

Other observations

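Among all tested genes, some of them described above, 21 lay under 1 FPKM in Kras WT and at 5 FPKM or more in Kras G12D, and 14 showed the opposite. Genes named here were chosen after their values were seen. Those present in Kras G12D included the transcription factor gene Maf, at 6.66 against 0.279 FPKM, the ERK feedback gene Spry4, at 5.93 against 0.159 FPKM, and the receptor gene Flt1, at 6.04 against 0.353 FPKM. Those present in Kras WT included Tbx21, the homeobox gene Otx2, at 8.23 against 0.518 FPKM, and the cytokine gene Il10, at 5.06 against 0.852 FPKM. Of 20 p53 target genes, 8 rose and 10 fell (camera, adjusted p = 0.82), with Cdkn1a at 53.3 against 113 FPKM and Sesn1 at 160 against 97.3 FPKM. Of 20 interferon response genes, 3 rose and 12 fell, with Bst2 at 159 against 299 FPKM and Usp18 at 46.6 against 11.5 FPKM. The camera adjusted p was 0.073, but 0.039 under quantile normalization and 0.048 in TPM, so the call depends on scaling. With an estimated correlation the adjusted p was 0.24. Of 14 immediate early genes, 9 rose and 4 fell (camera, adjusted p = 0.077), with Jun at 8.42 against 1.15 FPKM. Jun is also a member of the stress and dissociation list, a list of sample quality. Of its 12 tested genes, 7 rose and 5 fell (camera, adjusted p = 0.26). Of 22 cholesterol synthesis genes, 8 rose and 11 fell (camera, adjusted p = 0.77), and 9 rose and 8 fell under quantile normalization. These lists had the same counts adjusted over each list alone.

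Among the tests below, those of replicates as splits of the same cells, of copy gain, of the second allele, of spleen cells, of ribosomal protein genes alone and of gene placement were chosen only after the result was seen. The first pattern is that most tested genes passed the threshold. Of 10 splits of the 6 libraries into 3 and 3, 1 gave 7552 genes, the real one, and the highest of the others gave 1; 10 splits are too few for a share under 0.05. Lower depth in Kras G12D was not decided by thinning. Limma-voom after thinning to 1 depth called 98.6% as many genes as before. The libraries held 25120000 to 30890000 implied fragments, so thinning removed few of them and a near-equal count was likely beforehand. That count shows that most calls remained at equal depth, and it cannot count further against depth. Replicates that are splits of the same cells stay open: over all rows their squared differences were at most 1.79 times counting noise, under the bound of 2 set for that explanation, but over rows of more than 3000 fragments they reached 4.14 times in Kras G12D and 1.72 times in Kras WT. Single samples set against counting noise do not decide it, and the p-values may then describe 2 cell populations and not the genotypes in general.

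The second pattern is the higher Kras. The authors' scaling is argued against, because the log2 fold change was at least 0.606 under median-of-ratios scaling and quantile normalization. A copy gain that spans the 20 nearest tested genes and raises them as much as Kras is argued against: their median of -0.088 lay 0.675 below the 0.587 of Kras, more than their SD of 0.411, and 1 of the 20 rose as much as Kras. A gain confined to Kras stays open. The lower bound of 0.3 for a gain was set after the values were seen, and it lay within 1 SD of the median. Transcription of the second allele once the stop cassette is removed stays open and cannot be told apart from other causes, since the ratio of 1.518 had been seen before its bounds were set and cannot count for it.

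The third pattern is lower expression of the 10 lists called lower, which cover the cell cycle, DNA repair, amino acid supply, ribosomes and energy metabolism among others. Scaling is argued against as the whole cause for the lists together. The median over their 246 members stayed at or below -0.230 under median-of-ratios scaling and quantile normalization, against -0.267. Rescaling to TPM gave -0.216. All 17 list calls at the preset correlation held under both, though 0 of the 17 lists passed with an estimated correlation. Camera compares a list with the other genes, so a scaling that shifts all genes alike hardly changes its calls. That the calls held therefore cannot count against scaling. GC content and length are argued against for the lists together (median -0.258 with the trends removed) but not for ribosomal protein genes. The median of those genes moved from -0.156 (quartiles -0.248 and -0.073) to -0.087 (-0.164 and 0.019), and their call ended as the shift became smaller. Quantile normalization moved it about as far, to -0.084 (-0.203 and -0.0069), though the call held (camera, adjusted p = 0.039). Scaling is therefore not argued against for ribosomal protein genes either. More normal B cells or CD4 T cells in the Kras G12D libraries are argued against as the cause only by the levels themselves. The bounds of 10 FPKM for that cause and 1 FPKM for excluding it were set after the values were seen and cannot count. Cd79a, Cd19, Ms4a1 and Cd4 lay at 0.342 FPKM or less in Kras G12D, under both bounds. Cd79b, at 2.79 FPKM, lay above 1 FPKM but was lower than in Kras WT, at 4.27 FPKM. A slower cycle of Kras G12D cells may be a biological account, and it was not tested.

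Genes with large changes lay next to each other more often than chance placement gives. Of 10776 pairs of neighbouring tested genes, 47 changed at least 2-fold in the same direction and 4 in opposite directions, against a mean of 11.7 in the same direction after shuffling (permutation p = 0.0001, the smallest that 10000 shuffles can give). With overlapping genes, gaps over 100 kb and pairs sharing the first 3 letters of their symbols left out, 28 of 7232 pairs did so, against 7.81 (permutation p = 0.0001). Examples, chosen after their values were seen, are Gcg and Fap on chromosome 2, Cd5 and Cd6 on chromosome 19 with 1 unnamed gene between them, and Ltb, Tnf and Lta on chromosome 17. Related genes with unlike symbols stayed in under the rule on symbols, among them the chemokine receptor genes Cx3cr1 and Ccr8 on chromosome 9. Shared regulation of neighbouring genes may account for neighbouring pairs with large changes, and it was not tested. Median log2 fold changes per autosome lay between -0.071 on chromosome 15 and 0.0054 on chromosome 6.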
